A study of Mus musculus with 12 samples.

How the data were processed

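Single-nucleus RNA was measured in 12 kidney libraries of male C57/BL6J mice whose skin had received phenylarsine oxide, a trivalent organic arsenical that binds neighbouring thiol groups, or the ethanol vehicle alone. The deposited values were raw UMI counts per gene and barcode, as the authors obtained them with Cell Ranger on the mouse genome mm10; the file headers gave version 6.0.0. The labels did not state whether intronic reads were counted or how barcodes were called. Each table listed 32285 genes, and the 12 tables together held 92227 barcodes. The labels gave acute kidney injury as the disease state of every library, vehicle included, so this entry separated no groups. No sequencing batch, date or pairing of animals was given.

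Nuclei with at least 300 detected genes, at least 500 UMIs and at most 5% mitochondrial UMIs were kept, which left 91970. Doublets were predicted in each library by comparing nuclei with simulated pairs, at an expected rate of 0.8% per 1000 nuclei, and where the caller marked under 0.5% of a library the expected share was taken. Clustering used all libraries together: counts were scaled to 10000 per nucleus, log transformed and reduced to 30 principal components of 1992 variable genes, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1, which gave 31 clusters. Clusters with more than 40% predicted doublets were left out, and predicted doublets were left out of the sums, so 82825 nuclei were used. A cluster took the name of a cell type when at least 3 of its markers were detected in at least 10% of nuclei and were at least 2-fold above the median cluster, with 10 CPM added to both. The names end in "-like" because they rest on markers alone. The naming of clusters was changed once, after the clusters had been seen and before any test was run: a fold over all other nuclei had left the most numerous proximal tubule clusters unnamed, and the median cluster took its place as the reference. A class was tested where every library held at least 20 of its nuclei, which gave 11 classes. The lymphocyte-like class had 16 nuclei in 1 library and entered only the comparison of shares.

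UMIs were summed per library and class. Proximal tubule-like sums held 12003800 to 18015447 UMIs from 2899 to 3582 nuclei per library. Genes passed filterByExpr by group, libraries were scaled by TMM, and 1 quasi-likelihood model in edgeR 4.0.16 with 4 group means was fitted over the 12 libraries; the groups shared an estimate of the spread, since single groups held only 2 to 4 libraries. Contrasts were phenylarsine oxide against vehicle at 6 h and at 24 h, the mean of both, the 24 h effect minus the 6 h effect, and vehicle at 24 h against vehicle at 6 h. Adjusted p is by Benjamini-Hochberg over all genes tested in a class, with a threshold of 0.05; all tests were two-sided. Log2 fold changes are given ± SE, taken as the size of the change divided by the square root of the F statistic of its test. This SE restates the test and is not a separate measure of precision. CPM (the usual unit, from the UMIs of the class) is given as mean ± SD over the libraries of a group. Gene lists were tested by camera in limma 3.58.1 on voom values with a preset correlation of 0.01 and, beside it, with an estimated correlation, adjusted over the 24 lists. Class shares, in percent of the nuclei left after doublets and doublet clusters were removed, were compared by an exact permutation of treatment within times over all 350 arrangements.

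The groups, tests, cell type markers, gene lists, rule for naming genes and alternatives were fixed before the data were examined; the rule for naming clusters, and the alternatives given below as added, were not among them. The lists were NRF2 antioxidant targets, metal response, arsenic handling, heat shock, unfolded protein and integrated stress response, tubular injury, oxidative phosphorylation, mitochondrially encoded transcripts, citrate cycle and pyruvate dehydrogenase, glycolysis, gluconeogenesis, fatty acid oxidation, PPAR alpha targets, amino acid catabolism, NAD synthesis, cholesterol synthesis, proximal tubule transport, inflammation, interferon response, p53 targets, glucocorticoid response, immediate early genes, hypoxia response and circadian clock. Some genes stand in more than 1 list. Genes were named by this rule: in proximal tubule-like nuclei at each time, up to 10 rises and 10 falls, largest first, among genes past the threshold with a mean of at least 10 CPM whose treated libraries all lay on one side of the vehicle libraries. In each list up to 4 members past the threshold were named, or else the member with the smallest p, as values only. Havcr1, Lcn2, Hmox1, Nqo1, Mt1 and Cdkn1a were always included. The other proximal tubule comparisons, and each time in the other classes, took the 3 largest rises and falls. Where fewer than 5 genes passed, the 5 with the smallest p could be given as values. Any other gene is marked as chosen after its values were seen. Single-gene results of 3 genes that the rule or a list would name are not reported here.

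Alternatives were DESeq2 size factors in edgeR, no filter beyond 1 count, DESeq2 1.42.0 with default settings, only the libraries of that time, doublets kept, stricter nuclei of at least 800 genes and 1000 UMIs with at most 1% mitochondrial UMIs, clustering at resolution 0.5, a log2 scale for shares, and leaving out each library in turn. Adding injured proximal tubule-like clusters to the proximal tubule was also planned, but no cluster took that name. After the values had been seen, a fit without the libraries labelled 24 h phenylarsine oxide replicate 38 and 6 h phenylarsine oxide replicate 43 was added, and beside it fits without each of the 12 pairs of one 24 h and one 6 h phenylarsine oxide library. The average over both times was planned for the proximal tubule alone and was added for the other classes after the values had been seen, with the naming rule of the proximal tubule average. The labels themselves were never changed.

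The procedure was tested on simulated data with 200 changed genes. At the spread of the 12 libraries it recovered 67.3% to 82% of genes given a log2 change of 2 in size and 20% to 36% of those given a change of 1, with 7 false calls at 6 h and 5 at 24 h. The simulated genes varied independently of each other. In the real libraries genes moved together, with an estimated correlation of 0.87 in the glucocorticoid response list at 6 h. These rates therefore need not hold for the 12 libraries. Gene coordinates came from GENCODE vM21 on GRCm38, matched by identifier; the annotation release behind the counts was not stated. UMI counts set a floor on rare transcripts, and nuclear RNA carries few mitochondrial transcripts. Transcripts free in the suspension enter all nuclei; calls in the other classes were therefore compared with genes at least 5-fold higher in the proximal tubule. Other tools were R 4.3.3, Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0, umap-learn 0.5.12, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.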

Results

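The 12 libraries fell into 4 groups by treatment and time of harvest. Vehicle at 6 h had 2 libraries, replicates 35 and 37, with 32559179 and 28230387 UMIs. Phenylarsine oxide at 6 h had 3, replicates 43, 45 and 47, with 30235626, 25593070 and 27077747 UMIs. Vehicle at 24 h had 3, replicates 31, 33 and 34, with 33029441, 27247704 and 23058758 UMIs. Phenylarsine oxide at 24 h had 4, replicates 38, 39, 41 and 42, with 30318268, 28429881, 26631769 and 24626414 UMIs. Median UMIs per nucleus ran from 2645 to 3979. Proximal tubule-like nuclei were the most numerous class, and the questions were which of their genes and which gene groups differed between phenylarsine oxide and vehicle at each time.

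At 6 h, Rgcc rose and Ctnna2 fell in proximal tubule-like nuclei. Rgcc (ENSMUSG00000022018, GRCm38 chromosome 14, 79288756 to 79301645), a regulator of the cell cycle, went from 1.24 ± 0.134 CPM (SD, n = 2) to 7.09 ± 2.03 CPM (SD, n = 3), a log2 fold change of 2.50 ± 0.29 with an adjusted p of 0.0385. Its level was low, under the 10 CPM of the naming rule, so it was named after its values were seen. Ctnna2 (ENSMUSG00000063063, chromosome 6, 76881637 to 77979699), an alpha-catenin of cell junctions, went from 514 ± 178 to 166 ± 23.7 CPM, a log2 fold change of -1.63 ± 0.20 with an adjusted p of 0.0385. For both genes, as the naming rule required of Ctnna2, the 3 treated libraries lay on one side of the 2 vehicle libraries. These were the 2 genes of 15820 past the threshold in edgeR; 1266 had an unadjusted p under the same value, and DESeq2 called 96, of which 43 were higher and 53 lower. The count was 0 without any one of replicates 31, 33, 34, 35, 39, 41, 42, 45 or 47 and with the 6 h libraries alone, 5 without replicate 38 and 12 without replicate 43.

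Stress genes that arsenicals are known to induce were high in some 6 h libraries and not in others. Hmox1, which degrades haem under oxidative stress, stood at 68.7 and 58.1 CPM in replicates 45 and 47, at 3.19 CPM in replicate 43, and at 6.20 and 23.3 CPM in the vehicle libraries (log2 fold change 1.56, adjusted p 0.786). Nqo1, a quinone reductase controlled by NRF2, stood at 123 and 90.2 CPM in replicates 45 and 47, at 40.4 CPM in replicate 43, and at 30.8 and 31.2 CPM in vehicle (1.44, adjusted p 0.591). Cdkn1a, the p53-controlled cell cycle inhibitor, stood at 11.3, 10.3 and 1.29 CPM in the same order of libraries and at 0.428 and 0.127 CPM in vehicle (4.69, adjusted p 0.412). The other genes fixed for display did not pass either. The log2 fold changes were 0.63 for the injury marker Havcr1 (adjusted p 0.933), 2.43 for the injury marker Lcn2 (0.665) and 0.63 for the metallothionein Mt1 (0.725).

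By list, 12 of the 24 gene groups stood higher at 6 h than other genes with the preset correlation, and 0 did with an estimated correlation, where their adjusted p ran from 0.308 to 0.628. No list had a member past the threshold over all genes. The glucocorticoid response list had the highest median log2 change, 2.25 (adjusted p 0.000298; adjusted p = 0.475 with an estimated correlation), and PPAR alpha targets, which include enzymes of fatty acid use, had a median of 1.78 (0.0184; adjusted p = 0.608 with an estimated correlation). Fatty acid oxidation had a median of 0.43 (0.0237; adjusted p = 0.628 with an estimated correlation) and immediate early genes one of 0.87 (0.0237; adjusted p = 0.608 with an estimated correlation). Gluconeogenesis had a median of 0.58 (1.89e-05; adjusted p = 0.308 with an estimated correlation), and 3 members passed when adjusted over the list alone, among them Got1 at 0.88 ± 0.17 and Slc37a4 at 0.83 ± 0.26. The interferon response had a median of 0.32 (0.012; adjusted p = 0.356 with an estimated correlation), with 5 members higher, among them Isg15 at 2.89 and Ifit3 at 2.04, and Irf1 lower at -1.58 when adjusted over the list alone. Tubular injury had a median of 0.52 (0.000298; adjusted p = 0.308 with an estimated correlation), with Cp, the copper-binding ceruloplasmin, at 1.52 ± 0.29 adjusted over the list alone. Medians were 0.40 for NRF2 antioxidant targets (0.00257), 0.31 for the unfolded protein and integrated stress response (0.0237), 0.28 for p53 targets (0.00402), 0.19 for amino acid catabolism (0.012) and 0.09 for the citrate cycle and pyruvate dehydrogenase (0.0237). With an estimated correlation these last 5 had adjusted p = 0.356, 0.356, 0.308, 0.308 and 0.308.

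The other 12 lists did not pass at 6 h. Their preset adjusted p was 0.115 for metal response, 0.0908 for arsenic handling, 0.254 for heat shock, 0.489 for oxidative phosphorylation, 0.0602 for mitochondrially encoded transcripts, 0.135 for cholesterol synthesis, 0.168 for proximal tubule transport, 0.212 for inflammation and 0.0938 for the circadian clock. In proximal tubule transport 2 members were lower when adjusted over the list alone, the dicarboxylate carrier Slc13a3 at -1.08 and the organic anion carrier Slc22a8 at -0.99. Sign depended on the summary in the 3 remaining lists. Glycolysis had a median of 0.10, a mean of -0.05 and a test upward (0.352), NAD synthesis a median of -0.05, a mean of 0.17 and a test upward (0.786), and the hypoxia response a median of -0.05, a mean of 0.35 and a test upward (0.352).

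Libraries of the phenylarsine oxide groups did not lie together in these lists. In mean log2 CPM of PPAR alpha targets, 6 h replicates 45 and 47 stood at 8.15 and 8.03 and replicate 43 at 3.98, with vehicle at 5.49 and 5.67. At 24 h replicate 38 stood at 8.04 and replicates 39, 41 and 42 at 4.27, 4.04 and 4.58, with vehicle at 4.52 to 4.71. The glucocorticoid response list split the same libraries, with 8.07 and 7.57 against 4.57 at 6 h and 8.02 against 4.14 to 4.45 at 24 h.

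**Figure D1:**
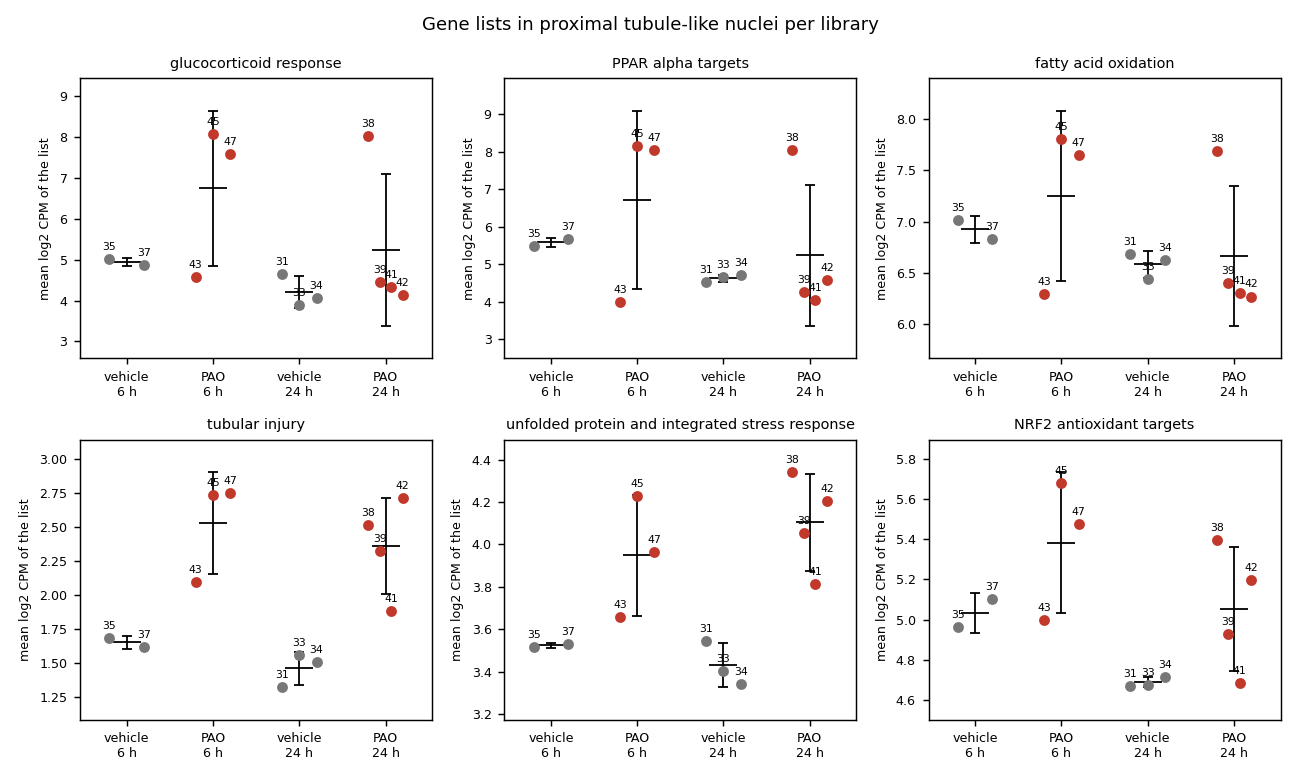
Mean log2 CPM of the members of 6 gene lists in proximal tubule-like nuclei, by group; each point is a library with its replicate number, the bar is the mean ± SD, red is phenylarsine oxide and grey is vehicle. PPAR alpha targets stand at 8.04 in 24 h replicate 38 and at 3.98 in 6 h replicate 43.

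At 24 h, 7 genes fell and 1 rose in proximal tubule-like nuclei. Creld2 (ENSMUSG00000023272, GRCm38 chromosome 15, 88819646 to 88826683), a chaperone of the endoplasmic reticulum, rose by a log2 fold change of 1.32 ± 0.16 (adjusted p 0.0364). Ctnna2 fell here too, from 623 ± 61.1 CPM (SD, n = 3) to 249 ± 11.5 CPM (SD, n = 4), a log2 fold change of -1.32 ± 0.17 (adjusted p 0.0364). The long noncoding RNA Sox2ot (ENSMUSG00000105265, chromosome 3, 34104270 to 34682619) went from 135 ± 13.9 to 48.3 ± 4.85 CPM, or -1.48 ± 0.15 (adjusted p 0.0125). The antisense RNA Gm15581 (ENSMUSG00000085264, chromosome 6, 17206823 to 17385604) went from 24.1 ± 9.10 to 3.09 ± 1.39 CPM, or -2.96 ± 0.41. Fam13c (ENSMUSG00000043259, chromosome 10, 70440481 to 70558736) went from 27.3 ± 7.64 to 9.25 ± 0.962 CPM, or -1.56 ± 0.22. Cacnb4 (ENSMUSG00000017412, chromosome 2, 52428320 to 52676831), a calcium channel subunit, went from 46.5 ± 3.81 to 20.8 ± 2.68 CPM, or -1.16 ± 0.17. Mettl24 (ENSMUSG00000045555, chromosome 10, 40683282 to 40811083), a predicted methyltransferase, went from 92.8 ± 12.8 to 46.6 ± 3.11 CPM, or -0.99 ± 0.13. Gm48867 (ENSMUSG00000112277) fell by 2.58 at a mean of 0.620 CPM; it and Creld2, at 7.77 CPM, were under the level of the rule and were named after their values were seen. The adjusted p of these last 4 falls and of Gm15581 was 0.0431.

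In Creld2 all 4 treated libraries lay on one side of the 3 vehicle libraries, replicate 38 included. The same held in the 6 falls of the rule, where it was a condition of being named and so no evidence of its own. In edgeR 8 of 15820 genes passed at 24 h. An unadjusted p under the threshold value was found for 1493, and DESeq2 called 181, of which 61 were higher and 120 lower. The count was 0 without any one of replicates 31, 33, 34, 39 or 41, 1 without replicate 42, 3 without replicate 45, 5 without replicate 47, 30 without replicate 43, 15 without the low count filter and 2 with the 24 h libraries alone. Of the 6 genes always shown, 0 passed. The log2 fold changes were 4.81 for Lcn2 (adjusted p 0.175), 2.45 for Cdkn1a (0.497), 1.99 for Hmox1 (0.618), 0.97 for Nqo1 (0.552), 0.78 for Mt1 (0.515) and 0.04 for Havcr1 (0.995). Lcn2 was at 0.126 to 0.165 CPM in vehicle and at 0.505, 3.22, 2.45 and 11.6 CPM in replicates 38, 39, 41 and 42. Hmox1 stood at 45.5 CPM in replicate 38 and at 3.82, 4.02 and 8.22 CPM in replicates 39, 41 and 42.

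**Figure D2:**
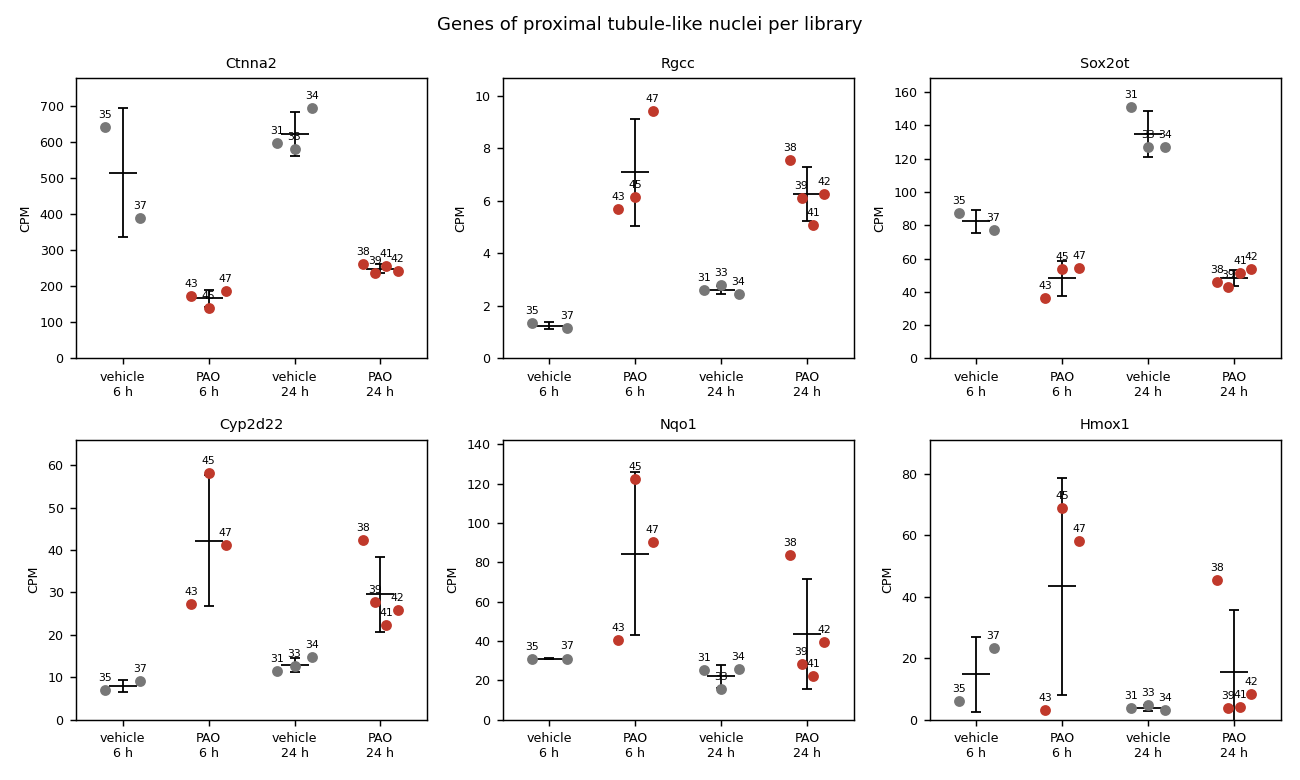
CPM of Ctnna2, Rgcc, Sox2ot, Cyp2d22, Nqo1 and Hmox1 in proximal tubule-like nuclei, by group; each point is a library with its replicate number, the bar is the mean ± SD, red is phenylarsine oxide and grey is vehicle. Ctnna2 and Sox2ot separate the groups at 24 h, as the naming rule required, while Hmox1 stands at 45.5 CPM in 24 h replicate 38 and at 3.19 CPM in 6 h replicate 43.

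At 24 h, the lists of the unfolded protein and integrated stress response, tubular injury, heat shock and inflammation had positive medians and passed with the preset correlation alone. In the unfolded protein and integrated stress response, Creld2 rose among 25 measured members, and 9 were higher when adjusted over the list alone, among them the chaperones Hspa5 at 1.60 ± 0.35, Hsp90b1 at 1.52 ± 0.29 and Pdia4 at 1.36 ± 0.23. The list had a median of 0.83 (adjusted p 3.27e-09; adjusted p = 0.0592 with an estimated correlation). Tubular injury had a median of 0.80 (1.93e-07; adjusted p = 0.0823 with an estimated correlation). None of its 24 members passed over all genes and 8 did when adjusted over the list alone, among them Clu at 1.13 ± 0.21, Cp at 1.29 ± 0.24 and the complement gene C3 at 2.52 ± 0.50. Heat shock had a median of 0.54 (1.56e-09; adjusted p = 0.151 with an estimated correlation), with Hspa4l at 0.73, Hspb1 at 1.69, Dnajb1 at 0.86 and Hspe1 at 0.52 higher when adjusted over the list alone. Inflammation had a median of 0.53 (7.67e-05; adjusted p = 0.191 with an estimated correlation), with C3 and Lcn2 higher when adjusted over the list alone.

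The count of lists past the threshold at 24 h was 11 with the preset correlation, each of them upward, and 0 with an estimated correlation. The other 7 had medians of 0.33 for NRF2 antioxidant targets (0.000114), 0.08 for oxidative phosphorylation (0.00407), 0.27 for the interferon response (0.00647), 0.14 for the citrate cycle and pyruvate dehydrogenase (0.00679), 1.56 for the glucocorticoid response (0.0176), 0.87 for immediate early genes (0.0337) and 0.27 for gluconeogenesis (0.0358). With an estimated correlation they had adjusted p = 0.302, 0.588, 0.353, 0.191, 0.674, 0.681 and 0.452. Without replicates 38 and 43, 3 of the 11 no longer passed with the preset correlation: the glucocorticoid response had a median of 0.06 (0.854), immediate early genes one of 0.08 (0.854) and gluconeogenesis one of 0.20 (0.553). In mean log2 CPM, immediate early genes stood at 3.51 in replicate 38, at 1.82, 1.29 and 1.64 in replicates 39, 41 and 42, and at 1.51 to 1.81 in vehicle. The preset adjusted p of lists that did not pass was 0.0854 for metal response, 0.602 for arsenic handling, 0.137 for glycolysis, 0.459 for fatty acid oxidation, 0.14 for PPAR alpha targets, 0.167 for amino acid catabolism, 0.0617 for cholesterol synthesis, 0.281 for proximal tubule transport, 0.0617 for p53 targets and 0.801 for the circadian clock. Signs differed in 3 more of these. Mitochondrially encoded transcripts (0.773) had a median of -0.00 and an upward test, and NAD synthesis (0.773) and the hypoxia response (0.928) had medians of 0.12 and 0.05 and a downward test.

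Over both times together, 139 genes changed in proximal tubule-like nuclei, 41 upward and 98 downward. The largest rises by the naming rule were Mgst1 (ENSMUSG00000008540), a microsomal glutathione transferase, at 1.89 ± 0.36 (adjusted p 0.0421), the cytochrome Cyp2d22 (ENSMUSG00000061740) at 1.79 ± 0.22 (0.0112) and the annexin partner S100a10 (ENSMUSG00000041959) at 1.67 ± 0.33 (0.0421). Cyp2d22 went from 8.03 ± 1.44 CPM (SD, n = 2) to 42.2 ± 15.5 CPM (SD, n = 3) at 6 h and stood at 29.6 ± 8.81 CPM (SD, n = 4) with phenylarsine oxide at 24 h; its log2 fold changes at the single times were 2.39 (adjusted p 0.124) and 1.19 (0.162). The largest falls were the sodium leak channel Nalcn (ENSMUSG00000000197) at -3.10 ± 0.46 (0.0166), Gm15581 at -2.73 ± 0.32 (0.00991) and the integrin regulator Apbb1ip (ENSMUSG00000026786) at -2.27 ± 0.39 (0.0301). Nalcn went from 46.2 ± 6.98 to 3.59 ± 1.32 CPM at 6 h and from 32.0 ± 17.1 to 5.60 ± 5.27 CPM at 24 h. Ctnna2 changed by -1.48 on average (0.00288) and Rgcc by 1.88 ± 0.18 (0.00360).

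Among list members, the average called 2 genes of the unfolded protein and integrated stress response, Creld2 and Pdia4, each at 0.99, and 3 of tubular injury, Cp at 1.40, Clu at 0.80 and C3 at 2.15. It called the small heat shock protein Hspb1 at 1.49 and Got1, of gluconeogenesis, at 0.61. The organic anion carrier Slc22a8 fell, at -0.73, and in the interferon response Ifit2 rose, at 1.35, and Irf1 fell, at -1.07. DESeq2 called 581 genes, 249 upward and 332 downward, and 2347 genes had an unadjusted p under the threshold value. Replicate 43 lowered the count most, since 497 genes passed without it. The count was 128 without replicate 38, 87 without 39, 81 without 41, 51 without 31, 50 without 42, 40 without 37, 36 without 47, 33 without 33, 31 without 45, 23 without 34 and 1 without 35.

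The difference between the 24 h and the 6 h effect, and the background difference between vehicle at 24 h and at 6 h, each gave 0 genes in edgeR. Unadjusted p fell under the threshold value for 402 and 565 genes, and DESeq2 called 0 and 2. No gene was therefore shown to respond differently at the 2 times in the 12 libraries, Ctnna2 and Creld2 included.

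The libraries labelled 24 h phenylarsine oxide replicate 38 and 6 h phenylarsine oxide replicate 43 stood apart from their groups. Between libraries of proximal tubule-like nuclei, replicate 38 had a mean correlation across genes of 0.953 with its own group and 0.976 with the 6 h phenylarsine oxide group. Replicate 43 had 0.948 with its own group, 0.974 with 24 h phenylarsine oxide and 0.976 with the vehicle groups of both 6 h and 24 h. Genes are not independent replicates. The 6 h group set against replicate 38 held replicate 43, and the 24 h group set against replicate 43 held replicate 38. These means therefore do not show replicate 43 to be nearer to vehicle than to replicates 39, 41 and 42. Replicates 39, 41 and 42 had 0.974, 0.973 and 0.972 with their own group and up to 0.980, 0.979 and 0.973 with a vehicle group. Their own group held replicate 38, with which they had 0.957, 0.952 and 0.949. Each pair among replicates 39, 41 and 42 had 0.983, above these vehicle values. With their own group, 6 h replicates 45 and 47 had 0.964 and 0.967, and that group held replicate 43. They had 0.984 with each other and 0.945 and 0.950 with replicate 43. A fit without replicates 38 and 43 was therefore added after seeing the data. Since these libraries were chosen by their values, its p-values are not independent evidence, and its genes are given as chosen after their values were seen.

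Without both libraries, 1853 of 15711 genes passed at 6 h, 1031 upward and 822 downward, with 2 treated and 2 vehicle libraries at that time. Higher members numbered 12 of 13 in the glucocorticoid response (median 2.78; adjusted p = 0.0343 with an estimated correlation), 13 of 15 in PPAR alpha targets (2.36; adjusted p = 0.0119 with an estimated correlation) and 18 of 25 in fatty acid oxidation (0.77; adjusted p = 0.0343 with an estimated correlation). Pdk4, which restrains pyruvate oxidation, had a log2 fold change of 5.49 ± 0.32, with 1255 and 1185 CPM in replicates 45 and 47 and 36.6 and 17.2 CPM in vehicle; left out of that fit were 4.95 CPM in replicate 43 and 1199 CPM in 24 h replicate 38. Cyp4a14, a fatty acid hydroxylase, had 5.51 ± 0.92 and stood at 1704 and 2123 CPM in replicates 45 and 47, at 14.2 CPM in replicate 43 and at 1724 CPM in replicate 38. The glucocorticoid-induced factor Zbtb16 had 6.89 ± 0.53, and the gluconeogenic G6pc had 3.20 ± 0.26. Stress genes passed as well, with Cdkn1a at 5.18 ± 0.55, Hmox1 at 2.10 ± 0.49, Nqo1 at 1.77 ± 0.29 and Sesn2 at 2.79 ± 0.22. In proximal tubule transport 8 of 30 genes were lower and 1 higher (median -0.30; adjusted p = 0.177 with an estimated correlation), and the endocytic receptor Lrp2 had -0.98 ± 0.17. The transporter Slc22a28 had -3.39 ± 0.29, at 69.1 and 127 CPM in replicates 45 and 47, 1118 and 921 CPM in vehicle, 1841 CPM in replicate 43 and 167 CPM in replicate 38.

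At 24 h the same fit called 257 genes, 94 upward and 163 downward. Of the 25 genes in the unfolded protein and integrated stress response, 6 were higher (median 0.61; adjusted p = 0.429 with an estimated correlation), among them Hspa5 at 1.81 ± 0.26, Hsp90b1 at 1.72 ± 0.19 and Pdia4 at 1.52 ± 0.19. Hspa5 stood at 101, 64.0 and 122 CPM in replicates 39, 41 and 42, at 47.8 CPM in replicate 38 and at 27.3 to 28.1 CPM in vehicle. Tubular injury had 6 higher members of 24 (0.72; adjusted p = 0.429 with an estimated correlation), among them Lcn2 at 5.21 ± 0.85, Cp at 1.39 ± 0.17 and Clu at 1.25 ± 0.20. Lower were the organic anion carrier Slc22a7 at -2.82 ± 0.44, the receptor kinase Alk at -2.47 ± 0.24, G6pc at -0.98 ± 0.20 and Angptl4, a PPAR-controlled inhibitor of lipoprotein lipase, at -1.26 ± 0.20. In that fit 1143 genes differed between the 6 h and 24 h effects, 454 upward and 689 downward. PPAR alpha targets had a median difference of -2.78, with 12 lower (adjusted p = 0.0146 with an estimated correlation), and fatty acid oxidation one of -0.95, with 16 lower (adjusted p = 0.0284 with an estimated correlation).

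Both genes called at 6 h and all 8 called at 24 h in the 12 libraries also passed, in the same direction, without replicates 38 and 43, as did 138 of the 139 called on average. The other was the apolipoprotein gene Apoa4. That fit reused the remaining libraries and called far more genes, so this overlap is not independent support. Leaving out any of the other 11 pairs of one 24 h and one 6 h phenylarsine oxide library gave 0 to 16 genes at 6 h and 0 to 23 at 24 h.

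**Figure D3:**
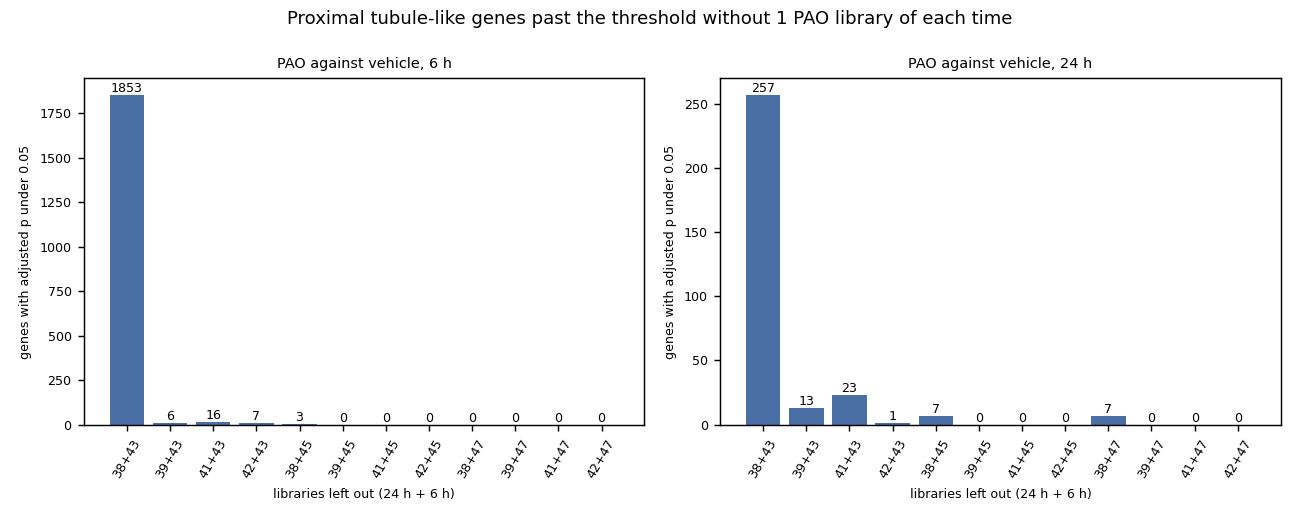
Number of proximal tubule-like genes with an adjusted p under 0.05 at 6 h and at 24 h when 1 phenylarsine oxide library of each time was left out, for all 12 pairs; bars start at 0. Leaving out replicates 38 and 43 gave 1853 genes at 6 h and 257 at 24 h, and the other pairs gave at most 16 and 23.

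In the other cell classes few genes passed at a single time. In thin limb-like nuclei at 6 h, 11 genes changed, 3 upward and 8 downward. Zbtb16 rose by 4.07 ± 0.71 (adjusted p 0.0224) from 18.5 ± 3.70 CPM (SD, n = 2) to 318 ± 177 CPM (SD, n = 3), and the scaffold gene Akap12 rose by 2.19 ± 0.38 (0.0224). The aldose reductase Akr1b3, which makes sorbitol as an osmolyte, fell by 2.39 (0.0057) from 2144 ± 785 to 410 ± 144 CPM, the Notch ligand Jag1 fell by 2.06 (0.0443) and the exchange factor Vav2 fell by 1.85 (0.0429). In myeloid-like nuclei at 6 h, the prostaglandin-degrading enzyme Hpgd fell by 1.85 and the glycosyltransferase Extl3 rose by 1.36 ± 0.23 (both 0.0299). At 24 h the glucocorticoid-induced Fkbp5 rose by 3.34 ± 0.58 and the transporter Slc6a15 fell by 2.81 (both 0.0333), and the matrix protein Tgfbi rose by 1.48 ± 0.27 (0.036). Fkbp5 stood at 2525 CPM in 24 h replicate 38, at 3002 and 2523 CPM in 6 h replicates 45 and 47 and at 566 to 773 CPM in the other phenylarsine oxide libraries.

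At 24 h, the stromal-like class gave 3 rises, the oncostatin M receptor Osmr at 1.09 ± 0.15 (adjusted p 0.0186), the lectin Clec2d at 1.60 ± 0.20 (0.01) and the matrix gene Adamtsl2 at 1.75 ± 0.23 (0.01). Osmr went from 301 ± 27.3 CPM (SD, n = 3) to 642 ± 53.3 CPM (SD, n = 4). Endothelial-like nuclei gave 2 falls, the scaffold gene Dlg2 at -1.63 ± 0.18 and the catenin Ctnna3 at -1.38 ± 0.16 (both 0.00353). In podocyte-like nuclei the guidance gene Srgap3 rose by 2.17 ± 0.35 and the class I histocompatibility gene H2-Q6 fell by 1.97 (both 0.0211). None of the genes called at a single time in these classes was among those at least 5-fold higher in the proximal tubule. Replicates 38, 45 and 47 again stood apart in the endothelial-like and stromal-like classes. They had 16, 8 and 18 nuclei in one endothelial-like cluster, where the other 9 libraries had 615 to 918, and 6, 5 and 10 in one stromal-like cluster, where the others had 276 to 448. Another endothelial-like cluster went the other way, with 1041, 1073 and 1020 nuclei of replicates 38, 45 and 47 and 160 to 265 of each other library. Another stromal-like cluster also held more nuclei of each of replicates 38, 45 and 47 than of any other library. The low counts therefore do not show a loss of endothelial-like or stromal-like nuclei.

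Over both times together, 8 of these 10 classes gave genes past the threshold; this comparison and its genes were added after the values were seen. Stromal-like nuclei gave 150 genes, 100 upward and 50 downward, among them the complement gene C6 at 3.53 ± 0.64 (adjusted p 0.02), Zbtb16 at 3.17 ± 0.61 (0.026), the interferon-induced Ifit1 at 3.14 ± 0.58 (0.0218) and the sorting nexin Snx31 at -2.25 ± 0.32 (0.00634). Zbtb16 stood there at 2336 CPM in 24 h replicate 38 and at 329 CPM in 6 h replicate 43. Myeloid-like nuclei gave 88 genes, 51 upward and 37 downward, with Fkbp5 at 3.37 ± 0.43 (0.00101) and the ubiquitin ligase Rnf24 at -2.40 ± 0.39 (0.00416). Rnf24 stood at 93.4 CPM there and at 374 CPM in the proximal tubule, close under the 5-fold level taken for transcripts free in the suspension. Endothelial-like nuclei gave 50 genes, 31 upward and 19 downward, with Zbtb16 at 4.44 ± 0.83 (0.0373), the complement gene C7 at 2.10 ± 0.39 (0.0373) and the syntrophin Sntb1 at -1.68 ± 0.22 (0.00958). Thick ascending limb-like nuclei gave 29 genes, 19 upward and 10 downward, with the phosphodiesterase Pde10a at 2.41 ± 0.40 (0.0334), and distal convoluted and connecting tubule-like nuclei gave 25, 18 upward and 7 downward, with the kinase Camk2b at 2.34 ± 0.32 (0.0193).

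Fewer than 10 genes passed over both times in each of the remaining classes. Thin limb-like nuclei gave 9, 5 upward and 4 downward, with Zbtb16 at 3.30 ± 0.44 (adjusted p 0.00164) and Fkbp5 at 2.85 ± 0.45 (0.00706). Fkbp5 stood at 119 CPM there and at 475 CPM in the proximal tubule, close under the 5-fold level, as Rnf24 did in myeloid-like nuclei. Podocyte-like nuclei gave 7, 6 upward and 1 downward, with Srgap3 at 2.26 ± 0.28 (0.000605) and H2-Q6 at -1.25 ± 0.25 (0.0405). Intercalated cell-like nuclei gave 4, with Sh3rf1 at 0.82 (0.0335), 4933417O13Rik at 0.95 (0.0428), Gm44129 at 1.97 (0.0428) and Gm13986 at -1.14 (0.0335). Principal cell-like and parietal epithelial-like nuclei gave 0 in edgeR, with 780 and 204 genes at an unadjusted p under the threshold value and 13 and 2 in DESeq2. Genes at least 5-fold higher in the proximal tubule made up 5 of the 150, 11 of the 88, 5 of the 50, 2 of the 29, 3 of the 25 and 1 of the 9 in the order given, and 0 of the 7 and 0 of the 4. These were 3.33%, 12.5%, 10%, 6.90%, 12%, 11.1%, 0% and 0% of the called genes, against 4.32%, 3.69%, 5.59%, 4.64%, 5%, 2.95%, 4.32% and 3.89% of all genes tested in these classes. Cyp4a14, at 466 CPM in the proximal tubule, was such a gene and was among the 3 largest rises in the distal convoluted and connecting tubule-like, endothelial-like, myeloid-like and thick ascending limb-like classes, as was Ctnna2, at 371 CPM, among the falls in all of these but the endothelial-like.

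All genes called over both times in these classes also passed, in the same direction, without replicates 38 and 43. Here too that fit reused the remaining libraries and called more genes, so the overlap is not independent support. Leaving out 1 library moved the counts by more than 1.5 times in most cases. The stromal-like count ran from 2 without 37 to 713 without 43 and moved so without all but 38, 39 and 42. The myeloid-like count ran from 3 without 35 to 213 without 43 and moved so without 31, 33, 34, 35, 37, 38, 43 and 45. The endothelial-like count ran from 3 without 35 to 635 without 43 and moved so without all but 38 and 39. The thick ascending limb-like count ran from 0 without 35 to 368 without 43 and moved so without all but 39 and 42. The distal convoluted and connecting tubule-like count ran from 0 without 33, 34 or 35 to 135 without 43 and moved so whichever of the 12 was left out. The thin limb-like count ran from 4 without 31, 33 or 37 to 153 without 43 and moved so without 35, 39, 41, 42 and 47 too. The podocyte-like count ran from 1 without 35, 37 or 47 to 18 without 43 and moved so without 34 and 45 too. The intercalated cell-like count ran from 0 without 31, 34, 35, 39 or 45 to 41 without 43 and moved so without 33, 37, 38, 42 and 47 too. The principal cell-like count of 0 became 2 without 31 or 37, 3 without 41 and 5 without 43, and the parietal epithelial-like count of 0 became 1 without 43.

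Single libraries moved the small counts at 6 h and 24 h. The thin limb-like count at 6 h was 6 without replicate 31, 1 without 33, 5 without 34, 2 without 35, 0 without 37, 31 without 38, 5 without 41, 19 without 42, 138 without 43, 5 without 45 and 1 without 47. The myeloid-like count of 2 at 6 h became 0 without any one of 31, 33, 34, 35, 45 or 47, 5 without 37, 7 without 39 or 42, 62 without 38 and 70 without 43. At 24 h the myeloid-like count of 3 became 0 without 31, 33 or 39, and 9 without 38 or 43. The endothelial-like count of 2 became 4 without 45, 5 without 38 and 6 without 43. The podocyte-like count of 2 became 0 without 33, 34, 39 or 41 and 1 without 42. The stromal-like count of 3 became 0 without 33, 34 or 41, 5 without 31, 35, 37 or 39, 7 without 38 and 58 without 43.

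In edgeR 0 genes passed at either time in the distal convoluted and connecting tubule-like, intercalated cell-like, principal cell-like, parietal epithelial-like and thick ascending limb-like classes. Unadjusted p fell under the threshold value for 761 and 749, 462 and 388, 714 and 622, 172 and 116, and 1168 and 870 genes at 6 h and 24 h in that order. DESeq2 called 13 and 14, 3 and 2, 0 and 1, 0 and 0, and 57 and 24 genes. At 6 h, 0 genes passed in the endothelial-like, stromal-like and podocyte-like classes (1164, 1141 and 276 unadjusted; 32, 70 and 4 in DESeq2). At 24 h, 0 passed in the thin limb-like class (405 unadjusted; 0 in DESeq2).

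Shares of the cell classes were compared to ask whether phenylarsine oxide changed the make-up of the nuclei. None passed. Lymphocyte-like nuclei were 0.417 ± 0.0758% (SD, n = 3) against 0.702 ± 0.311% (SD, n = 2) of vehicle nuclei at 6 h, and 0.317 ± 0.0719% (SD, n = 4) against 0.926 ± 0.372% (SD, n = 3) at 24 h. The mean difference was -0.447 percentage points, with an exact permutation p of 0.00571 and an adjusted p of 0.0686; the smallest p the design allows is 0.00286. With the stricter nuclei filter the difference was -0.237 points and passed, at an exact adjusted p of 0.0343. Proximal tubule-like nuclei were 46.0 ± 1.44% against 47.1 ± 0.477% at 6 h and 46.5 ± 1.09% against 46.7 ± 0.320% at 24 h, and the adjusted p of every class but the lymphocyte-like was 0.558 or more.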

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

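The clock-gene tests were written before their result was seen; the reading of the clock scale class by class, the depth test, the fit without replicates 38 and 43 and all counts of other splits of the libraries were chosen after. In groups of 4, each measure was tested for a library far from the other 3, which chance gives in about 1 in 20 groups for a single measure. Such a library was found in 9 of 61 tests, 8 of them replicate 38. The 61 measures came from the same libraries, shared genes and included genes named from these data. Their count therefore cannot be set against that rate. In proximal tubule-like nuclei at 24 h with phenylarsine oxide, replicate 38 stood at 8.04 in mean log2 CPM of PPAR alpha targets (the other 3 at 4.04 to 4.58), at 8.02 in the glucocorticoid response (4.14 to 4.45), at 7.69 in fatty acid oxidation (6.27 to 6.40) and at 5.20 in the hypoxia response (4.53 to 4.59). It stood at 45.5 CPM of Hmox1 (3.82 to 8.22) and at 21.2 CPM of Mt1 (12.1 to 13.4). Its median UMIs per nucleus were 3158 (2767 to 2818), and its median mitochondrial share was 0.0514% (0.0736 to 0.0773%). Nalcn was at 13.4 CPM in replicate 41 and at 2.19 to 3.75 CPM in the others.

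Replicates 38 and 43 may carry each other's labels, or a pair of animals may have responded unlike their groups. Clock genes of the vehicle libraries set a scale from 0 at 6 h to 1 at 24 h, on which an exchange needed replicate 38 low and replicate 43 high; they stood at -0.115 and 0.497. These are medians over 11 classes, and by them the scale was not usable for treated animals, since 6 h replicate 47, which no other measure put in doubt, stood at 0.731. Class by class, 2 of the 11 placed all 5 phenylarsine oxide libraries not in doubt on their labelled sides, and both placed replicates 38 and 43 as an exchange needs, at -0.668 and 1.45 in thick ascending limb-like and at -0.383 and 0.866 in parietal epithelial-like nuclei. So did 3 more classes that placed 4 of the 5, among them the proximal tubule-like with -1.57 and 0.601; the other 6 placed 2 or 3 of the 5 and did not. The parietal epithelial-like scale rested on only 5 clock genes, with its 6 h vehicle libraries at -0.382 and 0.382. The name of this class was weak too. In mean log2 fold over the median cluster, its parietal epithelial markers scored 2.69 and adipocyte markers 2.67. Of the adipocyte markers only Plin1 and Pparg were raised, under the 3 a name needs. At resolution 0.5 the class was absent. The positions of replicates 38 and 43 in the classes that placed them so go with an exchange but do not settle it. Per1 stands in both the clock list and the glucocorticoid response list, which set replicates 38, 45 and 47 apart. A response like that of replicates 45 and 47 could therefore also place replicate 38 low, whatever its time of harvest. The classes were singled out after their values were seen, and clock genes of treated animals could lie outside the scale. In the proximal tubule 6 h replicates 45 and 47 stood at -1.69 and -1.16, where the 6 h vehicle libraries stood at 0.2 and -0.2. An exchange and an unusual response of single animals therefore cannot be told apart. Depth was asked in 2 ways, both chosen after the values were seen. By the first, depth needed either library outside the other phenylarsine oxide libraries in UMIs per nucleus. Both lay outside, at 3158 and 3080.5 against 2694 to 2818, so that criterion was met. By the second, libraries of like depth should move alike in PPAR alpha targets. They lay apart by 4.06, when the 5 vehicle libraries spanned 1.15. This argues against depth for that list, whose values were already known. The biological reading, a delayed or early response of single animals, was tested only on that scale and stays open.

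Of the 35 splits of the 24 h libraries into 4 and 3, only the labels themselves gave 8 proximal tubule-like genes (highest other 0). A share of 1 in 35 is the smallest these libraries allow, and the splits were chosen after the values were seen. The labels thus stood out in this class taken alone, which does not exclude chance. The endothelial-like count of 2 (highest other 1) and the myeloid-like count of 3 (highest other 2) were also reached by 1 split. So was the podocyte-like count of 2 (highest other 1). The margin was 1 gene, nothing was adjusted over the 11 classes, and splits other than the labels reached up to 5 genes elsewhere. Chance cannot be excluded for these counts. Nor can it be for the stromal-like count of 3, which 2 splits reached (highest other 3). The same holds for the 11 gene lists, which 12 splits reached (highest other 16). In 6 classes the count was 0, which all 35 splits reach by construction, so the splits say nothing there; the highest other was 1 in distal convoluted and connecting tubule-like, 5 in intercalated cell-like, 2 in principal cell-like, 3 in thin limb-like, and 0 in parietal epithelial-like and thick ascending limb-like nuclei. For the average over both times, 2 of 100 drawn splits reached 139 genes, the labels always being 1 of them. The other gave 665, more than the labels, so this draw does not exclude chance. That split set replicates 38, 45 and 47 apart from the other phenylarsine oxide libraries, which points to a structure of the samples that the labels do not follow.

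The same 100 splits, the labels always among them, were counted for the average in the other classes, again without adjustment over classes. The myeloid-like count of 88 (highest other 30) and the thick ascending limb-like count of 29 (highest other 1) were reached by 1 split. That split was the labels themselves, which gave the highest count of those drawn. The stromal-like count of 150 (highest other 162), the endothelial-like count of 50 (highest other 390), the distal convoluted and connecting tubule-like count of 25 (highest other 44) and the podocyte-like count of 7 (highest other 33) were reached by 2, the other being the split that set replicates 38, 45 and 47 apart. In each of these classes that other split gave more genes than the labels, so chance is not excluded there. The intercalated cell-like count of 4 (highest other 17) was reached by 3 splits and the thin limb-like count of 9 (highest other 20) by 4. In a draw of 100 from 350 this lies too near 5 to exclude chance. The count of 0 in principal cell-like and parietal epithelial-like nuclei is reached by all 100 by construction, so the splits say nothing there (highest other 26 and 50). The split that set replicates 38, 45 and 47 apart also gave the highest other in intercalated cell-like nuclei; where it called several times the real count, as there and in endothelial-like and podocyte-like nuclei, it points to a structure of the samples.

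The effect of phenylarsine oxide differed between 24 h and 6 h in 7 gene lists by a test of the difference with the preset correlation, and in 0 with an estimated correlation. The median difference in log2 change was 0.64 for heat shock (adjusted p 1.24e-11; 0.158 with an estimated correlation), 0.22 for the unfolded protein and integrated stress response (0.00115; 0.189) and 0.48 for inflammation (0.0144; 0.548). It was -0.32 for amino acid catabolism (0.000191; 0.158), -0.29 for gluconeogenesis (0.00366; 0.433), -0.43 for cholesterol synthesis (0.00366; 0.872) and -0.34 for arsenic handling (0.0263; 0.187). Without replicates 38 and 43, 4 of the 7 passed again in the same direction with the preset correlation: heat shock at 0.64 (0.00173), amino acid catabolism at -0.32 (0.0223), gluconeogenesis at -0.51 (0.00115) and arsenic handling at -0.31 (0.0439). The unfolded protein and integrated stress response (0.32; 0.442) and inflammation (0.01; 0.672) did not pass, and cholesterol synthesis reversed to 0.61 (0.0353). Its mean log2 CPM at 6 h was 4.97 in replicate 43, 3.43 and 3.35 in replicates 45 and 47, and 3.89 and 3.62 in vehicle. With an estimated correlation 0 of the 7 passed in that fit. Heat shock stood at much the same mean log2 CPM with phenylarsine oxide at both times, 4.65 to 5.06 at 24 h and 4.68 to 4.99 at 6 h. Vehicle stood at 4.12 to 4.47 at 24 h and, in replicates 35 and 37, at 4.61 and 5.15 at 6 h. The heat shock difference thus lay in the vehicle libraries, which were unlike each other at 6 h.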

How the results depend on the processing

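The fits without replicates 38 and 43 and without every other such pair, and the average over both times outside the proximal tubule, were chosen after seeing the data; every other alternative was planned. DESeq2 size factors in edgeR left all 77 named results past the threshold and all 375 others on their side of it. Of the 77, DESeq2 lost 4, resolution 0.5 lost 12 of the 76 it gave, stricter nuclei lost 14 and doublets kept lost 23; only the libraries of that time lost 14 of the 27 it applied to. Leaving out 24 h vehicle replicate 33 or 34 each lost 57, the most for any library. Without replicate 43, without both 38 and 43, or without the low count filter, all 77 passed. Of the 375 not past the threshold, 107 passed with DESeq2 and 159 without the low count filter. Without both 38 and 43, 283 passed in the same direction. The naming rule was also run on that last fit, so the 375 include genes chosen because they passed in it. The 283 was therefore in part set by the choice of genes. A library left out can leave 1 vehicle library at 6 h, whose spread is then assumed to be that of the other groups. No cluster was named injured proximal tubule-like, so that alternative gave no value, and at resolution 0.5 the lymphocyte-like and parietal epithelial-like classes were absent. The cause of the changes below was not tested.

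Without a filter on low counts, the counts at 6 h and 24 h were 162 and 132 in distal convoluted and connecting tubule-like, 268 and 191 in endothelial-like, 55 and 34 in intercalated cell-like, 150 and 93 in myeloid-like, 100 and 71 in principal cell-like, 8 and 45 in parietal epithelial-like, 53 and 39 in podocyte-like, 500 and 409 in stromal-like, 362 and 264 in thick ascending limb-like and 171 and 43 in thin limb-like nuclei, and 15 at 24 h in the proximal tubule. With DESeq2 they were 13 and 14 in distal convoluted and connecting tubule-like, 32 and 44 in endothelial-like, 3 and 2 in intercalated cell-like, 25 and 9 in myeloid-like, 4 and 5 in podocyte-like, 70 and 72 in stromal-like, 57 and 24 in thick ascending limb-like and 96 and 181 in proximal tubule-like nuclei, 27 at 6 h in thin limb-like and 1 at 24 h in principal cell-like nuclei. In the proximal tubule DESeq2 gave 581 genes on average over both times and 2 between the vehicle groups.

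With only the libraries of that time, the proximal tubule gave 0 at 6 h and 2 at 24 h, intercalated cell-like 3 at 24 h, myeloid-like 14 at 6 h, podocyte-like 2 at 6 h, stromal-like 10 at 24 h and thin limb-like 1 at 6 h. With doublets kept, myeloid-like gave 6 at 6 h and 0 at 24 h, and podocyte-like 6 at 24 h. With stricter nuclei, intercalated cell-like gave 1 at 24 h, myeloid-like 0 at 6 h, podocyte-like 1 at 24 h and thin limb-like 3 at 6 h, and 1 class share passed. At resolution 0.5, myeloid-like gave 0 at 6 h and 23 at 24 h, and at 6 h principal cell-like gave 1, stromal-like 1 and thin limb-like 4. With an estimated correlation, 0 gene lists passed at either time.

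Without replicates 38 and 43, the counts at 6 h and 24 h were 370 and 36 in distal convoluted and connecting tubule-like, 1331 and 167 in endothelial-like, 265 and 77 in myeloid-like, 54 and 5 in podocyte-like, 1853 and 257 in proximal tubule-like, 1132 and 188 in stromal-like, 881 and 69 in thick ascending limb-like and 207 and 3 in thin limb-like nuclei. At 6 h they were 76 in intercalated cell-like, 11 in principal cell-like and 2 in parietal epithelial-like nuclei. The proximal tubule then gave 1481 genes on average, 1143 that differed between times and 17 between the vehicle groups, and with an estimated correlation 3 lists at 6 h and 0 at 24 h. Log2 changes at 24 h reversed in Angptl4 from 1.44 to -1.26, Eci2 from 0.26 to -0.60, G6pc from 0.77 to -0.98, Gm15441 from 1.10 to -1.88 and Igfbp1 from 2.21 to -1.86. Of 96 list medians in the proximal tubule, 15 changed sign, and 5 of these passed in that fit with the preset correlation and not with an estimated one: PPAR alpha targets at 24 h went from 1.48 to -0.25 (preset adjusted p 0.0216), fatty acid oxidation at 24 h from 0.23 to -0.19 (0.00285), and cholesterol synthesis from 0.39 to -0.41 at 6 h (0.0172), from 0.13 to -0.19 on average (0.0288) and from -0.43 to 0.61 in the difference between times (0.0353). Of the lists past the threshold in the 12 libraries, 10 of 12 at 6 h, 8 of 11 at 24 h and 4 of 7 in the difference also passed there in the same direction.

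Leaving out 1 library at a time gave 0 to 12 genes at 6 h, 0 to 30 at 24 h and 1 to 497 on average in the proximal tubule, and 10 to 14 lists at 6 h and 8 to 14 at 24 h. At 6 h it gave 0 to 3 in distal convoluted and connecting tubule-like (1 without 38), 0 to 19 in endothelial-like (6 without 38), 0 to 17 in intercalated cell-like (3 without 38), 0 to 70 in myeloid-like, 0 to 1 in principal cell-like and in parietal epithelial-like, 0 to 3 in podocyte-like (2 without 43), 0 to 278 in stromal-like (82 without 38), 0 to 45 in thick ascending limb-like (1 without 47) and 0 to 138 in thin limb-like nuclei. At 24 h it gave 0 to 1 in distal convoluted and connecting tubule-like and in thin limb-like, 2 to 6 in endothelial-like (4 without 45), 0 to 9 in myeloid-like, 0 to 3 in podocyte-like (1 without 42), 0 to 58 in stromal-like and 0 to 4 in thick ascending limb-like nuclei (1 without 47). It left the genes that differed between times, the vehicle genes and the class shares at 0. The 24 h counts of intercalated cell-like, principal cell-like and parietal epithelial-like nuclei stayed at 0 too. For class shares too few arrangements remain for a single class to pass after adjustment, so their 0 does not show stability.

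On average over both times outside the proximal tubule, counts are given for distal convoluted and connecting tubule-like, endothelial-like, intercalated cell-like, myeloid-like, principal cell-like, parietal epithelial-like, podocyte-like, stromal-like, thick ascending limb-like and thin limb-like nuclei, in that order. Without a filter on low counts they were 399, 747, 90, 347, 114, 22, 67, 920, 658 and 191. With DESeq2 they were 99, 264, 17, 89, 13, 2, 22, 290, 188 and 32. Without replicates 38 and 43 they were 322, 1215, 50, 288, 5, 3, 32, 1022, 743 and 125. Leaving out 1 library at a time gave 0 to 135, 3 to 635, 0 to 41, 3 to 213, 0 to 5 (2 without 31), 0 to 1, 1 to 18, 2 to 713, 0 to 368 and 4 to 153. With stricter nuclei, endothelial-like gave 25, intercalated cell-like 2 and thick ascending limb-like 54; with doublets kept, intercalated cell-like gave 0, podocyte-like 14, thick ascending limb-like 12 and thin limb-like 5; at resolution 0.5, myeloid-like gave 191 and thick ascending limb-like 46.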

Other observations

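Within the proximal tubule-like class, libraries filled different clusters. One cluster, led by the lactate carrier Slc5a12 together with Gldc, Cyp4a14 and G6pc, held 1510, 1519 and 1648 nuclei of replicates 38, 45 and 47 and 154 to 454 of each other library. Another, led by the lipid genes Cyp4a14, Pdk4 and Cyp4a10, held 1093, 1136 and 1240 nuclei of the same libraries and 27 to 148 of the others. A cluster led by the transport genes Slc13a3, Slco1a1, Slc7a13 and Slc22a28 held 73, 42 and 107 nuclei of these 3 and 894 to 1375 of the others. The clusters were drawn from the same counts as the genes above and no test was made of their shares, since these libraries were singled out after their values were seen.

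The acute phase genes Saa1 and Saa2 of the inflammation list were too low to be tested. In proximal tubule-like nuclei 24 h phenylarsine oxide replicate 41 held 52 and 65 UMIs of them, and no other library held more than 4 of Saa1 or 5 of Saa2. Ccl2, a chemokine of the same list and also below the filter, had 28 UMIs in 6 h phenylarsine oxide replicate 45 and at most 8 in any other library. These genes were chosen after their values were seen.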
